A study of Yarrowia lipolytica with 16 samples.

How the data were processed

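RNA of Yarrowia lipolytica, an oil-accumulating yeast, was hybridised to 16 spotted 2-colour arrays. Each array set RNA of cells grown with a low amount of 1 sulfur source against RNA of cells grown with 1000 times more of the same source. The sources were methionine and sulfate (10 mM against 10 µM) and cystine, the disulfide of cysteine (1 mM against 1 µM). The labels give 2 repetitions for methionine, 3 for cystine and 3 for sulfate, and the series design calls them biological experiments, each with a dye swap. Per the labels' protocols, cells were kept in exponential growth in a defined medium by transfer to fresh medium, total RNA was extracted with Trizol, and cDNA was labelled with Alexa647 (red) or Alexa555 (green) after priming with anchored oligo(dT). The low sulfur RNA was green on the arrays before the swap and red on the swapped arrays, and every ratio was turned to low over high.

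The deposited intensity values were the mean and median pixel brightness of each spot and of its local background in both colours. Per the file headers, they came from Agilent Feature Extraction 9.1.3.1 with a protocol for arrays of another maker, and the processed signals had been background-subtracted and LOWESS dye-normalized with a smooth factor of 0.25. The deposited series matrix holds log2 values whose making is not given in the sources used here. In each column they followed, to within 5e-06, a lowess curve (span 0.3) of log2 red over green median signal against mean log2 signal, with the sign turned on swapped arrays. Their correlation across spots with normalized log2 ratios lay between -0.0992 and 0.0849. They hold the trend that a normalization removes, not the genes' ratios, so the planned use of them as an alternative was not run. Their column medians ran from -0.988 to 0.912, so that the columns are not centred.

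The methionine arrays held 13020 spots and the others 13376. The difference was 356 spots named "false". Genes are named by locus tags of the earlier genome annotation, for 6404 genes, of which 6401 had 2 spots and 3 had 4. The scanner files mark no control spots, so spots whose name holds no locus tag were treated as controls: 174 for foreign sequences, 144 of them luciferase, 16 named Actine and 16 named MFE. None of the 6404 tags matched the reference gene table used here (8689 genes), which carries another strain's tags, and no file gives a function. Of 17 gene lists fixed before the data were examined, 13 therefore had no members, and 2 had 1 member each. Gene names and functions of 19 loci listed by tag come from that plan, not from the files. A further list of 8 loci for sulfate assimilation and methionine synthesis was written from memory after the files were received and before any ratio was computed. Its membership is background knowledge that no file checks.

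Mean signals were corrected against median local background with normexp (offset 50), and log2 ratios were normalized within each array by loess (span 0.3), with controls and spots flagged as outliers at weight 0. Outlier spots were left out, saturated spots were not. Spots of a gene were averaged, and the 2 arrays of a dye-swap pair were averaged to 1 replicate. A gene measured on only 1 array of a pair kept that array's ratio, so that dye bias was not averaged out for it. A single limma 3.58.1 model (R 4.3.3, with files read by the package data.table, version 1.17.8) held the 8 repetitions with a mean for each source, so that the sources share 1 estimate of the spread per gene, with 5 residual degrees of freedom for 6365 genes and 3.72 prior degrees of freedom. Contrasts were the 3 sources, their pairwise differences and their mean. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Lists with at least 5 members were tested with camera (preset correlation 0.01), adjusted over 3 lists within each contrast. An estimated correlation and fry were the alternatives. The estimated correlation was -0.0173 for fatty acid synthesis, 0.0102 for beta-oxidation and -0.0689 for sulfate assimilation and methionine synthesis. Weaker results with it for the first and last of these lists therefore do not come from a higher correlation among genes. Every adjusted p for a gene is from this limma fit or, where an alternative is named beside it, from the limma fit under that alternative. Values after ± are SDs over repetitions.

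On simulated data with the spread of the 6404 genes and 200 changed genes, 99.0% of 2-fold changes were recovered for methionine, 100% for cystine and 99.0% for sulfate, and false calls made up 5.24%, 4.31% and 4.33% of calls. The simulation holds only spread that the model describes.

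The rule for named genes, fixed before the data were examined, took per source the 10 strongest rises and falls among called genes with an absolute log2 ratio of at least 1 and the same sign on every array. For pairs of sources it took 5 differences each way, and for the mean of the sources 10 genes each way called in all 3 in 1 direction. Because tags carry no name here, only the first 2 each way are printed, beside the listed loci. The planned filter on the scanner's flag for signal well above background removed 0 genes, as foreign-sequence spots carry the flag too. By a stricter measure chosen later, 3593 genes (56.1%) exceeded the 95th percentile of foreign-sequence spots in either channel on enough arrays. Luciferase spots make up most of the foreign-sequence spots, and on the array before the swap of methionine repetition 1 the percentile was 1157 in green and 967 in red, against 131 to 494 and 113 to 305 on the others. Over the 30 foreign spots without luciferase it was 88.0 to 475 in green and 78.3 to 411 in red, and 4185 genes (65.3%) exceeded it. On some arrays it rose without luciferase, as from 306 to 475 in green before the swap of methionine repetition 2. Where the text says that a channel exceeded the foreign-sequence spots, or was dim, it refers to the percentile with luciferase on the same array unless stated, and a ratio against a dim channel has no exact size. A slide held 1 array. The arrays were scanned on 3 days, none with arrays of more than 1 source, so differences between sources cannot be told apart from scan day or array series. Low and high RNA share each array, so this does not apply within a source. Cystine was compared at 1 mM against 1 µM and the other sources at 10 mM against 10 µM. Differences from cystine therefore also cannot be told apart from the amount supplied.

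Alternatives covered background correction, normalization, dim and outlier spots, dye orientation, the unit of replication, probe averaging, the fit, the threshold and leaving out each repetition. Alternatives that returned every reported value, or every value of another alternative, are left out where the text counts alternatives.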

Results

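The data were log2 ratios of transcript levels in low over high sulfur for 6404 genes, from 4 arrays for methionine, 6 for cystine and 6 for sulfate. The series asks how the yeast's gene expression responds to sulfur supply when the sulfur comes as methionine, cystine or sulfate. Median spot signals ranged from 102 to 318 in green and from 86.8 to 170 in red, at 1.48 to 2.94 times and 1.44 to 2.86 times the local background. The ratios of both arrays of a dye-swap pair correlated across genes at 0.754 to 0.902. Between repetitions of a source, the correlation across genes was 0.903 for methionine, 0.778 to 0.898 for cystine and 0.662 to 0.896 for sulfate. Genes are not independent replicates, and the number of arrays limits the precision.

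Low methionine raised all 8 loci listed for sulfate assimilation and methionine synthesis. YALI0B08140g stood at a log2 ratio of 5.99 ± 0.22 (n = 2 repetitions, adjusted p = 5.8e-07 by limma). YALI0B08184g stood at 5.13 ± 0.02 and YALI0D11176g at 4.44 ± 0.04. YALI0B08184g was measured on 2 of 4 arrays, 1 for each repetition, so that no dye-swap pair was averaged for it. The weakest rise in the list was that of YALI0E00418g, at 1.33 ± 0.19, 2.51-fold. The list's mean was 3.35, with an adjusted p of 1.01e-10 by camera and an adjusted p of 0.003 with an estimated correlation. In the high methionine channel YALI0B08140g exceeded the foreign-sequence spots on 1 of 4 arrays, and YALI0D25168g and YALI0E00836g on 0, so that the size of their ratios is not exact. After median centring 6 of the 8 rises were called. The functions of these loci are background knowledge recalled from memory, not a column of the files.

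Of the 7 listed genes of fatty acid and storage lipid synthesis, 6 fell with low methionine. They included both subunit genes of ATP citrate lyase, which supplies cytosolic acetyl-CoA, with ACL1 (YALI0E34793g) at -0.89 ± 0.04 and ACL2 (YALI0D24431g) at -0.80 ± 0.08. The fatty acid synthase genes FAS1 (YALI0B15059g) and FAS2 (YALI0B19382g) stood at -1.09 ± 0.08 and -1.05 ± 0.14, and the acetyl-CoA carboxylase gene ACC1 (YALI0C11407g) at -1.21 ± 0.49 (n = 2 repetitions each). The remaining gene, DGA1 (YALI0E32769g) for the last step of triacylglycerol synthesis, rose by 0.59 ± 0.33, with the same sign on 3 of 4 arrays; the call was lost in 6 of 23 alternatives, among them dye-swapped arrays (0.34) and leaving out repetition 2 (0.36). The falls lost calls too. OLE1 (YALI0C05951g), at -0.51 ± 0.12, lost its call in 6 of 23 alternatives. FAS2 lost it in 3, ACC1 and ACL1 in 2 each, and FAS1 and ACL2 in 1 each. Several alternatives, such as leaving out a repetition of another source, keep the methionine ratios as they were. FAS2, ACC1 and OLE1 lost their calls without either methionine repetition. Their ratios were -0.96, -0.87 and -0.43 without repetition 1, and -1.15, -1.56 and -0.60 without repetition 2. The loss for FAS1 was without repetition 1 (-1.03). After median centring only the falls of FAS1 and ACC1 were called, with log2 ratios of -0.52 to -1.18 for the other 4 genes that fell. The counts were the same when adjusted over the list alone. The list shifted down by camera with an adjusted p of 0.00462, and with an adjusted p of 0.0427 with an estimated correlation.

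Among 10 listed genes of peroxisomal beta-oxidation, the glyoxylate cycle and extracellular lipases, 2 rose and 2 fell with low methionine (3 and 2 adjusted over the list alone). MFE1 (YALI0E15378g), for the multifunctional beta-oxidation enzyme, stood at 1.00 ± 0.56, a call lost in 5 of 22 alternatives (0.60 without repetition 1). It was measured on 2 of 4 arrays, 1 for each repetition, so that no dye-swap pair was averaged for it. POX5 (YALI0C23859g) rose by 0.63 ± 0.22, a call lost in 8 of 23 alternatives. ICL1 (YALI0C16885g) fell to -0.56 ± 0.01, a call lost in 7 of 23. The acyl-CoA oxidase gene POX3 (YALI0D24750g) stood at -0.60 ± 0.26, a call lost in 3 of 23. POX3 exceeded the foreign-sequence spots on 1 of 4 arrays in high methionine (2 if luciferase spots are left out) and on 0 in low, so that its size is not exact. After median centring 0 genes rose and 1 fell. The list as a whole did not shift (adjusted p = 0.939 by camera; adjusted p = 0.942 with an estimated correlation). XPR2 (YALI0F31889g), which encodes the alkaline extracellular protease, rose by 1.82 ± 0.32, but its high methionine channel exceeded the foreign-sequence spots on 0 of 4 arrays, so that this size is not exact. It ranged from 0.93 to 2.52 over 23 alternatives, all of which kept the call. MHY1 (YALI0B21582g), a regulator of the yeast-to-hypha transition, was called at -0.37 ± 0.08, but neither channel exceeded the foreign-sequence spots on any of 4 arrays and the call was lost in 6 of 23 alternatives, so it is not read as a fall.

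In all, 1801 genes changed with low methionine, 889 higher and 912 lower, and 291 and 248 of them by at least 2-fold. The strongest rises among genes measured on every array were those of YALI0B17930g at 6.86 ± 0.12 and YALI0F22825g at 6.49 ± 0.62 (adjusted p = 8.1e-08 and 2.39e-06 by limma). In the high methionine channel both lay below the 95th percentile of foreign-sequence spots on all 4 arrays, so that neither the size of these ratios nor their rank is exact. The strongest falls were those of YALI0C15488g at -4.73 ± 0.24, whose low methionine channel exceeded those spots on 0 of 4 arrays (1 if luciferase spots are left out), and YALI0C15237g at -3.32 ± 0.28. Centring arrays on their median in place of loess gave 829 changed genes, and leaving out repetition 1 or 2 gave 1300 or 1071.

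Low cystine raised 5 of the 8 sulfate assimilation and methionine synthesis loci, 6 when adjusted over the list alone. YALI0B08140g stood at 3.15 ± 0.50 (n = 3 repetitions, adjusted p = 9.69e-06 by limma), or 8.87-fold, and YALI0B08184g at 2.69 ± 0.05, or 6.47-fold. YALI0D25168g stood at 1.54 ± 0.41. YALI0D11176g stood at 1.33 ± 0.06 but at -0.03 with median centring. There only the rise of YALI0B08140g was still called, at 1.75; YALI0B08184g (1.03, adjusted p = 0.0725 by limma), YALI0E16368g (0.51) and YALI0D25168g (0.94) lost their calls too, and YALI0E12683g was called at -2.06. YALI0E12683g, at -0.54 ± 0.51, did not pass. It was called as a fall at -0.83 without cystine repetition 1 and sulfate repetition 2, and at -0.54 with all 16 arrays and a dye effect. YALI0E00418g, at 0.44 and called in the reported fit only over the list alone, turned to -0.58 with median centring, not called. The list shifted up with an adjusted p of 4.49e-05 by camera and of 0.0195 with an estimated correlation, a call lost with median centring (adjusted p = 0.362, mean 0.17 against 1.30).

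Of the 7 fatty acid and storage lipid synthesis genes, 4 fell with low cystine, also when adjusted over the list alone. ACL2 (YALI0D24431g) stood at -1.08 ± 0.20, or 2.12-fold lower, FAS1 (YALI0B15059g) at -0.80 ± 0.25, ACL1 (YALI0E34793g) at -0.68 ± 0.23 and FAS2 (YALI0B19382g) at -0.64 ± 0.46 (n = 3 repetitions). ACC1 (YALI0C11407g), at -0.47 ± 0.39, did not pass. The list's adjusted p was 0.0106 by camera. With an estimated correlation, which at -0.0173 lay below the preset 0.01, camera gave an adjusted p of 0.0587 and the call was lost. After median centring 5 of the genes fell. XPR2 (YALI0F31889g) at 0.94 ± 0.26 and MHY1 (YALI0B21582g) at -0.36 ± 0.07 were called, with sizes that are not exact, as XPR2 in high cystine and MHY1 in low cystine exceeded the foreign-sequence spots on 0 of 6 arrays (MHY1 on 1 if luciferase spots are left out). Of the beta-oxidation list, 0 genes rose and 2 fell (1 adjusted over the list alone), POX3 (YALI0D24750g) at -0.38 ± 0.13 and POX2 (YALI0F10857g) at -0.38 ± 0.32. The call of POX3, whose low cystine channel exceeded the foreign-sequence spots on 0 of 6 arrays (1 if luciferase spots are left out), was lost in 5 of 23 alternatives, and that of POX2 in 15 of 23 (-0.20, adjusted p = 0.254 by limma, without cystine repetition 2). The list did not shift (adjusted p = 0.936 by camera and 0.939 as an adjusted p with an estimated correlation).

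With low cystine 1811 genes changed, 855 higher and 956 lower, with 185 and 134 by at least 2-fold. The strongest rises were those of YALI0D17622g at 5.32 ± 0.18 and YALI0D00407g at 5.25 ± 0.20 (n = 3 repetitions, adjusted p = 4.45e-08 and 3.98e-07 by limma). The strongest falls were those of YALI0D24816g at -3.29 ± 0.16 and YALI0C15237g at -2.55 ± 0.04. YALI0D17622g in high cystine and YALI0D24816g in low cystine exceeded the foreign-sequence spots on 0 of 6 arrays (YALI0D24816g on 3 if luciferase spots are left out), so that their size and rank may not be exact. The split of calls depended on the normalization, with 47.2% of calls higher after loess and 27.3% after median centring (406 higher and 1080 lower). Without cystine repetition 3 the count was 1159, and without repetition 2 it was 1202.

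Low sulfate raised 3 of the 8 sulfate assimilation and methionine synthesis loci, also when adjusted over the list alone. These were YALI0B08140g at 2.65 ± 0.36 (6.27-fold), YALI0B08184g at 1.85 ± 0.27 (3.61-fold) and YALI0D25168g at 0.89 ± 0.22 (n = 3 repetitions). With median centring YALI0B08184g stood at -0.30 and YALI0D25168g at 0.19, neither called, so that of the rises only that of YALI0B08140g was still called, at 1.03. YALI0D11176g, YALI0E12683g (-2.22) and YALI0E16368g (-1.36, against 0.26, and a called rise of 0.47 without cystine repetition 1 and sulfate repetition 2) were then called as falls. The other 5 loci did not pass, with YALI0D11176g at -0.14 ± 0.23. YALI0E12683g, at -0.49 ± 0.71, was called as a fall at -0.82 without sulfate repetition 2. The list did not shift (mean 0.60, or -0.80 with median centring and its direction turned, median 0.10, adjusted p = 0.199 by camera; adjusted p = 0.273 with an estimated correlation), whereas fry, which does not compare the list with other genes, gave an adjusted p of 0.00012.

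Of the 7 fatty acid and storage lipid synthesis genes, ACL1 (YALI0E34793g) and ACL2 (YALI0D24431g) fell with low sulfate, to -0.68 ± 0.23 and -0.71 ± 0.20 (2 genes adjusted over the list alone, n = 3 repetitions). FAS1 (YALI0B15059g) stood at 0.02 ± 0.45 and ACC1 (YALI0C11407g) at 0.08 ± 0.73, and neither passed; both turned to called falls with median centring, where 6 of the 7 genes fell, whereas ACC1 turned to a called rise of 0.51 (adjusted p = 0.0364 by limma) without cystine repetition 1 and sulfate repetition 2. The list's mean of -0.23 and its median of 0.02 differ in sign, and it did not pass (adjusted p = 0.199 by camera; adjusted p = 0.273 with an estimated correlation), but it passed with fry (adjusted p = 0.014) and with median centring (mean -1.30, adjusted p = 0.00112). None of the 10 beta-oxidation genes passed, with 0 rising and 0 falling (3 falling after median centring, where POX2 turned to -0.81), and the list did not shift (adjusted p = 0.616; adjusted p = 0.637 with an estimated correlation). XPR2 (YALI0F31889g) at 0.01 ± 0.02 and MHY1 (YALI0B21582g) at 0.05 ± 0.08 did not pass, and neither channel of either gene exceeded the foreign-sequence spots on any of 6 arrays.

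With low sulfate 1780 genes changed, 834 higher and 946 lower, with 153 and 135 by at least 2-fold. The strongest rises were those of YALI0D00407g at 5.28 ± 0.55 and YALI0D16137g at 4.92 ± 0.16 (n = 3 repetitions, adjusted p = 8.89e-07 and 6.84e-08 by limma). The strongest falls were those of YALI0E24167g at -2.53 ± 0.35 and YALI0F24431g at -2.19 ± 0.26. The high sulfate channel exceeded the foreign-sequence spots on 1 of 6 arrays for YALI0D00407g and on 0 for YALI0D16137g (1 if luciferase spots are left out). The low sulfate channel exceeded them on 0 for YALI0E24167g and on 2 for YALI0F24431g (4 if luciferase spots are left out). Neither the sizes nor the ranks of these genes are therefore exact. After median centring 32.4% of calls were higher, against 46.9% after loess (665 higher and 1390 lower). Without sulfate repetition 3 the count was 729, and without repetition 1 it was 915.

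**Figure D1:**
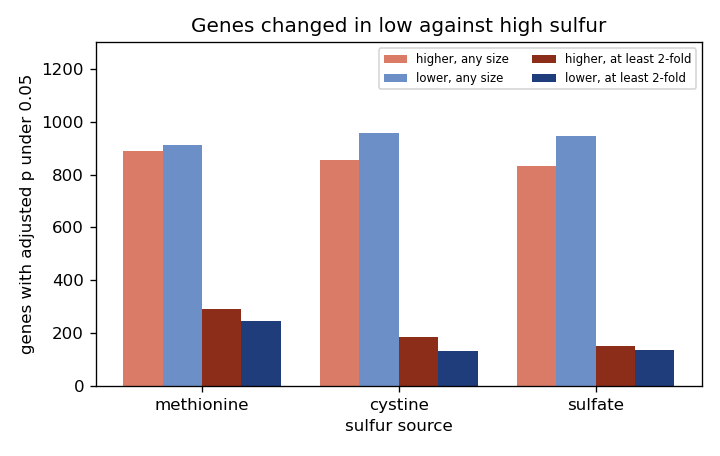
Bars give the number of genes (vertical axis) with an adjusted p under 0.05 for each sulfur source (horizontal axis), higher or lower in low sulfur, at any size and at 2-fold or more. The totals lie between 1780 and 1811, and methionine has the most genes at 2-fold or more, with 291 higher and 248 lower.

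**Figure D2:**
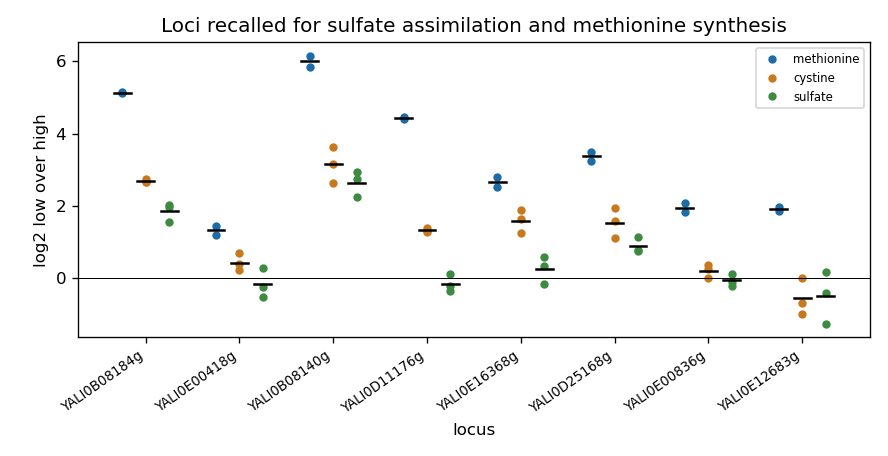
Points are biological repetitions and black lines their means, in log2 low over high sulfur (vertical axis), for the 8 loci recalled for sulfate assimilation and methionine synthesis (horizontal axis). All 8 rose with methionine, 5 with cystine and 3 with sulfate. After median centring 6, 1 and 1 rises were called. YALI0D11176g, YALI0E00418g and YALI0E00836g with cystine, and YALI0B08184g and YALI0E16368g with sulfate, then turned below 0.

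**Figure D3:**
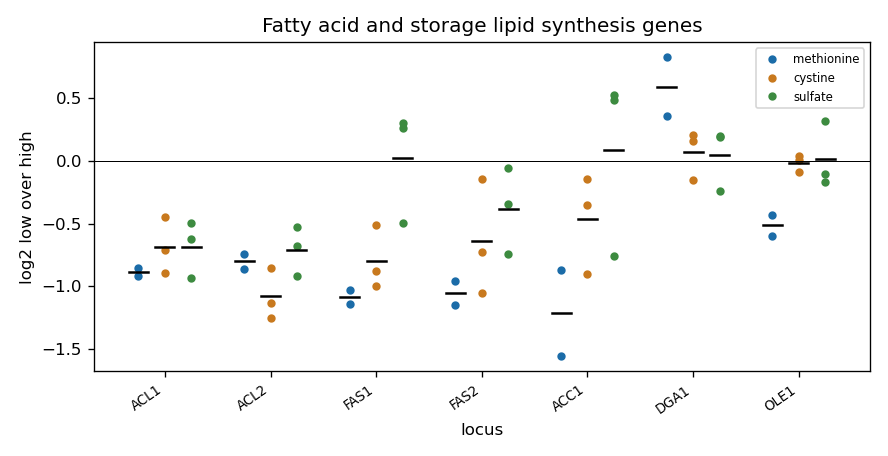
Points are biological repetitions and black lines their means, in log2 low over high sulfur (vertical axis), for the 7 listed genes of fatty acid and storage lipid synthesis (horizontal axis). ACL1 and ACL2 lie below 0 in every repetition, while FAS1 and ACC1 spread on both sides of 0 with sulfate and, like OLE1, turned to called falls there after median centring.

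A large set of genes responded whatever the source. In all 3 sources, 331 genes were called higher and 536 lower, 96 and 59 of them by at least 2-fold in each source. YALI0D00407g averaged 5.70 over the sources (SE 0.11, adjusted p = 3.27e-09 by limma) and YALI0D16137g 5.16 (SE 0.07, adjusted p = 7.41e-10). YALI0C15488g averaged -2.995 (SE 0.17) and YALI0C15237g -2.62 (SE 0.06). With methionine the high channel of YALI0D00407g and YALI0D16137g and the low channel of YALI0C15488g exceeded the foreign-sequence spots on 0 of 4 arrays (YALI0C15488g on 1 if luciferase spots are left out), so that these sizes are not exact. Over these 331 genes, the mean log2 ratio was 1.62 ± 0.03 with methionine (n = 2 repetitions), 1.25 ± 0.04 with cystine and 1.04 ± 0.07 with sulfate (n = 3 repetitions each). Over the 536 genes it was -0.90 ± 0.05, -0.78 ± 0.02 and -0.72 ± 0.06. These sets were picked by their calls, so their means are no independent estimate.

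Methionine and cystine shared 492 genes called higher, where independent lists would share 118.7, and 684 called lower, where they would share 136.1. Cystine and sulfate shared 524 and 671 genes, against 111.3 and 141.2 for independent lists. Methionine and sulfate shared 364 and 599 genes, against 115.8 and 134.7. The sources share an estimate of the spread per gene, which also raises the overlap. The mean of the sources passed the threshold for 2841 genes, 1460 higher and 1381 lower. After median centring, 37.4% of calls were higher, against 51.4% (918 higher and 1537 lower).

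Methionine and sulfate differed in more genes than the other pairs. The difference was called for 386 genes, with 289 more positive in methionine and 97 more negative. The sulfate assimilation and methionine synthesis loci differed as a list by a mean of 2.75 (adjusted p = 5.1e-15 by camera; adjusted p = 0.00128 with an estimated correlation). YALI0D11176g differed by 4.59 (SE 0.15, adjusted p = 1.9e-06 by limma). YALI0B05346g differed by 5.07 (SE 0.33), being at 4.49 ± 0.06 with methionine and at -0.58 ± 0.57 with sulfate. Its high methionine channel exceeded the foreign-sequence spots on 2 of 4 arrays, so that this size is not exact. YALI0C15488g differed by -2.85 (SE 0.42), a call lost in 3 of 24 alternatives, and YALI0F03344g by -2.15 (SE 0.42), a call lost in 8 of 24, with -0.30 after median centring and -0.98 on dye-swapped arrays. XPR2 (YALI0F31889g), dim in high sulfur with either source, differed by 1.81 (SE 0.18, adjusted p = 0.0012), or 0.87 and no longer called on dye-swapped arrays. FAS1 (YALI0B15059g) differed by -1.11 (SE 0.25, adjusted p = 0.0379), but by 0.25, in the other direction, after median centring, and the call held in 10 of 24 alternatives. The difference of ACL1 (YALI0E34793g), -0.20 (0.85 after median centring), did not pass (adjusted p = 0.493). The count fell to 69 after median centring and to 94 without methionine repetition 2, and rose to 891 without sulfate repetition 2.

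**Figure D4:**
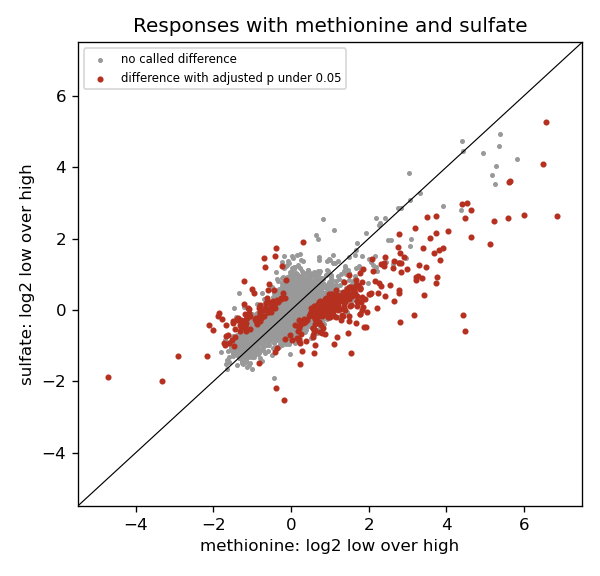
Each point is 1 of 6404 genes, by its mean log2 low over high with methionine (horizontal axis) and with sulfate (vertical axis); the line marks equal ratios. Red points are the 386 genes whose difference was called, 289 of them more positive with methionine.

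Methionine and cystine differed in 88 genes, 79 more positive in methionine and 9 more negative. Cystine was supplied in lower amounts than methionine or sulfate, so compound and amount cannot be told apart in any difference from cystine. The sulfate assimilation and methionine synthesis loci differed by a mean of 2.05 (adjusted p = 4.9e-15 by camera; adjusted p = 0.00127 with an estimated correlation). YALI0F13607g differed by 3.36 (SE 0.21, adjusted p = 0.000239 by limma) and YALI0B17930g by 3.31 (SE 0.24). Both were dim in high methionine, above the foreign-sequence spots on 0 of 4 arrays. YALI0C15488g differed by -2.34 (SE 0.42) and YALI0D05731g by -1.18 (SE 0.16), calls that were each lost in 10 of 24 alternatives, with -1.36 and -0.11 after median centring. The difference of XPR2 (YALI0F31889g), 0.88, did not pass (adjusted p = 0.0589). The count was 11 after median centring and 13 without methionine repetition 2.

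Cystine and sulfate differed in 48 genes, 34 more positive in cystine and 14 more negative. YALI0B05346g differed by 3.14 (SE 0.29, adjusted p = 0.00227 by limma), with 2.56 ± 0.42 in cystine, and YALI0E24167g by 2.71 (SE 0.19), with 0.18 ± 0.21 in cystine and -2.53 ± 0.35 in sulfate (n = 3 repetitions each). YALI0E24167g exceeded the foreign-sequence spots with cystine on 1 of 6 arrays in the high and 0 in the low channel (1 and 2 if luciferase spots are left out), so that a fall there may not have been seen. YALI0E11517g differed by -1.65 (SE 0.21) and YALI0B16368g by -1.62 (SE 0.19), calls lost in 8 and 4 of 24 alternatives. The sulfate assimilation and methionine synthesis loci differed by a mean of 0.70 (adjusted p = 8.55e-08 by camera; adjusted p = 0.0067 with an estimated correlation). XPR2 (YALI0F31889g), dim in high sulfur with either source, differed by 0.94 with an adjusted p of 0.0471, a call lost in 16 of 24 alternatives. The count was 5 after median centring and ranged from 7 without sulfate repetition 3 to 95 without sulfate repetition 2.

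Genes called in a source and different from both others numbered 70 for methionine (62 higher, 8 lower), 4 for cystine and 27 for sulfate. The spots' ratios before loess differed between repetitions in a way that bears on bright genes. In cystine repetitions 2 and 3 and sulfate repetitions 1 and 3, the brightest 20% of spots had median log2 ratios of -1.13, -1.03, -1.24 and -1.23, low on arrays of both dye orientations. The other repetitions lay between -0.22 and 0.09. Loess removes this trend and median centring keeps it. Leaving out cystine repetition 1 or sulfate repetition 2 leaves that source only repetitions with the trend, while both methionine repetitions had little of it. Counts of differences from methionine without them cannot be told apart from the trend.

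**Figure D5:**
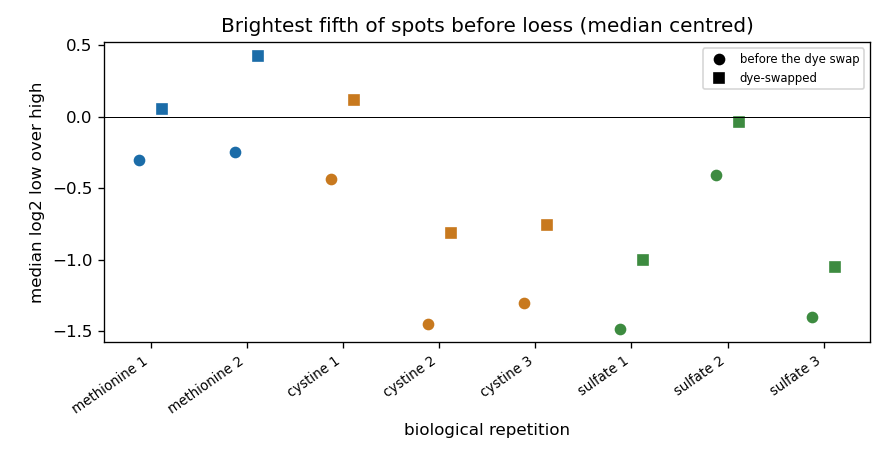
Median log2 low over high sulfur (vertical axis) of the brightest 20% of spots on each array, centred but without loess, by biological repetition (horizontal axis); circles are arrays before the dye swap and squares swapped arrays. Cystine repetitions 2 and 3 and sulfate repetitions 1 and 3 lie from -1.48 to -0.76 on both orientations.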

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

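The tests of dimmer arrays, of scan day and of the trend with signal in the sulfate repetitions were chosen after the patterns had been seen. So were those of exchanged labels and of a wrong source label. The tests of a trend left by the normalization and of noise or dye bias concern repetitions picked by their shared deviation. They therefore also came after that pattern had been seen. The remaining tests were not chosen after the patterns had been seen.

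Responses were larger with methionine than with sulfate: over the 867 genes changed in 1 direction in all 3 sources, the slope of sulfate on methionine log2 ratios was 0.646, and that of cystine on methionine 0.769. Among the brightest 20% of genes the slope was 0.655 (344 genes), with 0.633 to 0.679 over the 6 pairs of repetitions. This does not exclude compression of ratios on dim spots, as brightness was the mean signal of both channels. YALI0B17930g, for example, had a mean log2 signal of 11.08 but exceeded the foreign-sequence spots in high methionine on 0 of 4 arrays. With an offset of 10, the slope on the reported ratios of called genes was 1.18 for methionine and 1.23 for cystine and for sulfate. The trend with signal in 2 of the sulfate repetitions stays open, as only sulfate repetition 2 has little of it (slope at most 0.657) and that repetition deviates from its source. Whether this trend is technical or a real change of abundant transcripts was not tested, and if real, loess removes part of the change of bright genes such as FAS1 (YALI0B15059g), at 0.02 with sulfate but at -1.57 after median centring. Scan day and array series cannot be told apart from the source, since 0 scan days held arrays of both, and a biological difference between the sources stays open too, with methionine resting on 2 repetitions.

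Cystine repetition 1 and sulfate repetition 2 deviated together from the other repetitions of their sources, with a correlation of 0.665 across genes, and no group in the labels parts them from the others. Exchanged labels are argued against by cystine repetition 1. It correlated with its own source at 0.785 and with sulfate repetitions 1 and 3 at 0.562 (difference 0.223). Sulfate repetition 2 went the other way, at 0.784 with cystine repetitions 2 and 3 against 0.732 with its own source. The argument therefore rests on cystine repetition 1 alone. A wrong source label on either repetition is argued against by the 8 sulfate assimilation and methionine synthesis loci. On a scale from their own source (0) to another (1), both repetitions lay there at 0.0921 or less (at most 0.168 without any 1 locus). Over 747 and 1484 genes that differ from methionine without them, however, they lay at 0.483 and 0.44 towards methionine, with which they also correlated more (0.838 and 0.812) than with their own source (0.785 and 0.732), as sulfate repetition 2 did with cystine repetitions 2 and 3 (0.784). The source's other repetitions both picked those genes and set the scale's 0, so the selection itself can move these positions towards methionine. Positions of other repetitions were not computed. Noise or dye bias of single arrays is argued against by correlations of 0.542 and 0.56 between deviations on arrays of opposite dye orientation. Whether the trend with signal plays a part cannot be told apart here, since loess had flattened each array and removing a further trend moved little (0.672), while both repetitions had little of that trend before loess (-0.157 and -0.22 in the brightest 20% of spots); RNA quality, labelling and culture state were not tested and stay open.

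Changed loci lay beside each other in tag order more often than by chance. Of 6386 neighbouring pairs, 729 were called in the same direction in the mean of the sources, against a median of 629 and a maximum of 698 in 10000 shuffled orders, a share of 1e-04, the smallest these shuffles can give. Spots printed beside each other are argued against as the cause: tag neighbours not printed together correlated at 0.0871 across pairs and spots printed together at 0.0069, a difference of 0.0802. Tag order follows the naming of loci, since no coordinates were used. Shared hybridisation of neighbouring gene copies was not tested and stays open beside shared regulation, which is a hypothesis.

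The difference between sources was called for 386 genes (methionine minus sulfate), 88 genes (methionine minus cystine) and 48 genes (cystine minus sulfate). The log2 difference methionine minus sulfate was 5.07 for YALI0B05346g, 4.59 for YALI0D11176g, -2.85 for YALI0C15488g and -2.15 for YALI0F03344g. For methionine minus cystine it was 3.36 for YALI0F13607g, 3.31 for YALI0B17930g, -2.34 for YALI0C15488g and -1.18 for YALI0D05731g. For cystine minus sulfate it was 3.14 for YALI0B05346g, 2.71 for YALI0E24167g, -1.65 for YALI0E11517g and -1.62 for YALI0B16368g. The limits from dim channels given above apply to these sizes. Of 24 alternatives, 8 ended the call of YALI0F03344g, 10 each those of YALI0C15488g and YALI0D05731g for methionine minus cystine, and 8 that of YALI0E11517g. The sulfate assimilation and methionine synthesis list differed by means of 2.75, 2.05 and 0.70 in that order of pairs. The fatty acid list differed by -0.48 for methionine minus sulfate and by -0.29 for cystine minus sulfate (adjusted p = 0.0389 and 0.0336 by camera; adjusted p = 0.105 and 0.0981 with an estimated correlation); with median centring these were 0.53, in the other direction, and -0.11, neither called.

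For single arrays, 106 sets of 4 to 6 arrays were tested for an array far from the rest, and 4 such arrays were found, where chance gives about 1 in 20 sets. The arrays of a dye-swap pair are not independent. YALI0F22825g was lowest on the swapped array of methionine repetition 2 (5.29), and YALI0E15378g highest on that of cystine repetition 1 (1.06). YALI0E34793g was highest on the swapped array of cystine repetition 3 (-0.11), and YALI0B08184g on the array before the swap of the same repetition (2.88).

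Spots for luciferase, a foreign sequence, carried more signal than the 22 foreign spots not named luciferase, TetR or AlcR. Mean log2 signals were 7.21 ± 0.49 with methionine (those spots 6.14), 6.63 ± 0.10 with cystine (6.04) and 6.67 ± 0.13 with sulfate (6.03). TetR spots stood at 7.04, 6.39 and 6.78 in that order, above luciferase with sulfate. With methionine, luciferase stood at 7.56 in repetition 1 but at 6.865 in repetition 2, where TetR stood at 7.22. Log2 ratios of luciferase spots, low over high, were -0.15 ± 0.04 (n = 2 repetitions), 0.22 ± 0.28 and 0.42 ± 0.29 (n = 3 repetitions each).

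No other assignment of low and high within the 3 cystine repetitions called as many genes (1811, highest other 1), but 4 assignments are too few for a share under 0.05. The same holds for sulfate (1780, highest other 0) and for the 10 splits of the cystine and sulfate repetitions (48, highest other 0). For the mean of the sources, only the real one of 100 assignments drawn from 128 called as many genes (2841, highest other 1093), which excludes chance at that share.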

How the results depend on the processing

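The filter on foreign spots, the offset of 10 and leaving out cystine repetition 1 with sulfate repetition 2 were chosen after seeing the data; the other alternatives were planned. Counts below are genes for cystine minus sulfate, methionine minus sulfate and methionine minus cystine (48, 386 and 88 as reported), in that order; where the order is not given in full, the pair is named. Without background subtraction they were 18, 239 and 41, with the scanner's processed signals 22, 131 and 34, and with loess added 23, 143 and 41. Median centring gave 5, 69 and 11, and 829 genes for methionine. The brighter spot of each gene gave 55 for methionine minus cystine. Arrays before the dye swap gave 15 for cystine minus sulfate, and dye-swapped arrays 16, 229 and 25. All 16 arrays with a dye effect (pair correlation 0.284) gave 207, 865 and 322. Fitting channels apart, with no replicate block, gave 19, 175 and 35, sources fitted alone 16 for cystine minus sulfate and 253 for methionine minus sulfate, and eBayes with trend and robust 25 for cystine minus sulfate and 48 for methionine minus cystine. Without cystine 1 and sulfate 2 they were 76, 1487 and 748. That fit holds only cystine and sulfate repetitions with the trend of bright spots before loess, against methionine repetitions with little of it. Differences from methionine there cannot be told apart from the trend. An adjusted p under 0.01 gave 8, 112 and 19, with 1169, 1098 and 841 genes for methionine, cystine and sulfate. A log2 ratio of at least 1 gave 30, 182 and 53, with 539, 319 and 288 for the sources and 300 for their mean; fewer genes pass a stricter threshold by construction. Elsewhere the cause was not tested.

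With repetition number as a replicate block, the counts were 8, 105 and 12. Adding Aquantile, which cannot change ratios, gave the same counts. Deviations of same-numbered cystine and sulfate repetitions correlated at -0.556, -0.351 and 0.204, and those of methionine with the other sources at -0.0171 to 0.127. Deviations from a source's own mean depend on each other, and cystine repetition 1 and sulfate repetition 2 deviated together. The correlations therefore cannot tell whether the numbers pair samples.

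Leaving out each repetition in turn gave 1071 to 1884 genes for methionine, 1159 to 1940 for cystine, 729 to 1963 for sulfate and 2358 to 2895 for the mean, and 7 to 95, 94 to 891 and 13 to 127 for the differences. With 1 methionine repetition left, it is assumed to vary like the other sources. Of counts under alternatives that can move a value, each taken once, 105 stayed within 1.5 times the reported value and 72 did not.

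Median centring turned the sign of 27 values of listed genes, 8 of them called before or after: YALI0D11176g with cystine to -0.0312, and with sulfate YALI0F10857g to -0.81, YALI0B15059g to -1.57, YALI0C11407g to -1.15, YALI0C05951g to -0.85, YALI0B08184g to -0.30 and YALI0E16368g to -1.36, and FAS1 (YALI0B15059g) for methionine minus sulfate from -1.11 to 0.249. Median centring keeps the trend of bright spots that loess removes. Apart from these 8, over all counted alternatives, 1455 values for named genes kept their call and direction, 157 lost a call and 37 gained one. Another 1053 were not called either way, 101 of these with the sign turned. The uncalled values that median centring turned are among these 101. List means with median centring were 0.17 for sulfate assimilation and methionine synthesis with cystine (call lost) and -1.30 for fatty acid synthesis with sulfate (call gained), and the first list with sulfate turned from 0.60 to -0.80, not called either way. Of that list's loci, 6 rose with methionine, 1 with cystine and 1 with sulfate, and 1 and 3 fell with cystine and sulfate; of the fatty acid genes, 2, 5 and 6 fell. The fatty acid list with cystine lost its call at a mean of -0.52 both with an estimated correlation and over genes above the foreign spots. The fatty acid list for methionine minus sulfate (-0.48) turned to 0.53 with median centring, and lost its call with the processed signals (-0.44), with loess added to them (-0.46), on dye-swapped arrays (-0.42), with an offset of 10 (-0.47), without cystine 1 and sulfate 2 (-0.57) and with an estimated correlation (-0.48). For cystine minus sulfate (-0.29) it lost its call with the processed signals (-0.28), with loess added (-0.29), with median centring (-0.11), over genes above the foreign spots (-0.29), with an offset of 10 (-0.30), with an estimated correlation (-0.29) and with fry (-0.29). Leaving out each repetition gave -0.59 to -0.37 and -0.38 to -0.23; the first call was lost without methionine 1 (-0.37) or cystine 1, the second without methionine 1, methionine 2 or cystine 2 (-0.24). Fry called 2 lists with sulfate that camera did not, at means of -0.23 for fatty acid synthesis and 0.60 for sulfate assimilation and methionine synthesis.

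The planned flag filters and Aquantile moved nothing, the series matrix and slide block were not run, and low signal over background limits dim genes.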

Other observations

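Control spots named Actine and MFE, left out of the gene tests, also differed between repetitions. Actine spots stood at log2 low over high of 0.46 ± 0.28 with methionine (n = 2 repetitions), -0.06 ± 0.37 with cystine and -0.46 ± 0.43 with sulfate (n = 3 repetitions each). MFE spots stood at 1.33 ± 0.26, 0.29 ± 0.53 and 0.18 ± 0.50. The MFE spots were highest within cystine in repetition 1 (0.89) and within sulfate in repetition 2 (0.67), the same repetitions that deviated together across genes. Actine spots were highest there too (0.34 and 0.04, against -0.39 and -0.13, and -0.73 and -0.68, in the others). Luciferase spots were lowest there (-0.10 and 0.09, against 0.34 and 0.43, and 0.64 and 0.53). The others are the repetitions with the trend of bright spots before loess, and whether the 2 are linked was not tested. Actine and MFE spots were bright, with mean log2 signals of 8.69 to 10.02, and sequence on them was not analysed here.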
